A study of Homo sapiens with 2 samples.

How the data were processed

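Total RNA of TE-1 cells, an established human oesophageal squamous carcinoma line, was measured on 2 single-colour Cy3 NimbleGen expression arrays, 1 array for the empty pcDNA3.1 vector and 1 for the vector carrying PAX2. Per the labels' protocols, RNA was taken with Trizol 24 h after the transfection, and labelling followed the array maker's standard procedure. The arrays were summarised with RMA, per the submitters' processing notes. The software version, the background correction, the between-array step and the number of arrays normalised together are not given in the sources used here. The deposited values are intensities on the linear scale, 1 per feature and array. Per the file headers, a deposited count of probes stands beside each intensity: it was 3 for 45031 of 45033 features, and an extra row summarises 5000 random-sequence probes. Each file also holds a number called a standard error whose meaning is not stated and which was not used. The deposited series table repeats the intensities of the per-array files in all 45034 rows. Gene names and coordinates come from the array's design on build HG18, per the file headers.

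Features were named through their gene identifier. Of the 45033 features, 42947 carried one, 38916 of these matched a symbol of the reference gene table (assembly GRCh38.p14, used for names and gene types only), and 4031 kept the name in the file. The other 2086 features had no gene and were left out. Log2 intensities of the features of a gene were averaged, which gave 23595 genes, 11731 of them with 1 feature. A gene was treated as measured if this mean reached the median of all features on at least 1 of the 2 arrays, which 11628 genes did. Differences are log2 of the PAX2-labelled array minus log2 of the control array, with no pseudocount. No further normalization was applied.

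With 1 array per group there is no replicate and therefore no p-value; differences describe these 2 arrays, and the number of arrays limits the precision. Genes were counted when they differed at least 2-fold. Measurement error was described by the difference between 2 features of the same gene and by the spread of 376 olfactory receptor genes, a family that epithelial lines mostly leave silent. Neither holds the variation between cultures or hybridisations. For 22 gene lists written from textbook knowledge, the median difference of the measured members was placed among 10000 random lists of the same size, drawn from 20 bins of mean log2 intensity; whole chromosomes were placed among 2000 such lists. Genes of a list are often regulated together, so random lists understate the spread that such a list can show by chance. The lists, the filter, the 2-fold threshold and the alternatives were fixed before the data were examined, except where stated.

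The genes named are PAX2; the 12 protein-coding genes with the largest computed increase and the 12 with the largest computed decrease among measured genes at least 2-fold different, in the same direction in every feature, without placeholder symbols (LOC, open reading frame, FLJ, KIAA, MGC, DKFZ, olfactory receptor); and, per list, up to 2 members each way past 2-fold, or else the measured member with the largest difference. Other genes are said to have been chosen after their values were seen, or stand as further examples of a list. Some genes are not reported here. The files hold no detection call. Therefore a gene at or below the 95th percentile of the olfactory receptor genes on 1 array (log2 7.07 on the control array and 7.15 on the PAX2-labelled array) was given only a lower bound for its fold, against that percentile; this rule was chosen after seeing the data.

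The alternatives were the series table, centring on array medians, quantile normalization, loess correction of the difference on brightness (fraction 0.3), the brightest feature of a gene, no filter, a filter at the 75th percentile, thresholds of 1.5-fold and 3-fold, an offset of 64 before the log, unmatched random lists and list means. The counting was tested on simulated data, in which the control array received differences resampled within bins of brightness and 200 of its measured genes were changed by known amounts. Of 50 genes raised by 1.5 on the log2 scale 94.0% were recovered as 2-fold higher, and of 50 lowered by 1.5 86.0% as 2-fold lower; with changes of 2.5 these shares were 100% and 92.0%. In the same simulation 276 of 11449 unchanged genes passed the 2-fold threshold. The resampled differences were those between the 2 arrays, so this count repeats the observed spread and gives no false-positive rate. The list placement put 4 of 100 unshifted lists of 15 genes outside the 2.5th to 97.5th percentile, and 95 of 100 lists shifted by 0.3 above it. The share of unshifted lists follows from how the range was set. All reported list medians were smaller in size than 0.3, and several lists held fewer than 15 measured genes. The recovery of shifted lists therefore does not hold for them. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6 were used.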

Results

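To find genes that PAX2 activates, TE-1 cells carrying a PAX2 expression vector were compared with TE-1 cells carrying the empty vector, 24 h after transfection. PAX2 is a paired-box transcription factor of kidney and urogenital development. Each group held 1 array, so no difference below has a replicate check. The median feature had an intensity of 205 on the control array and 210 on the PAX2-labelled array, 9.96 and 10.9 times the level of the random-sequence probes (20.6 and 19.3). Across the 45033 features, log2 intensities of the arrays correlated with Pearson's r = 0.978; features are not independent replicates. The median difference of the 11628 measured genes was 0.02 on the log2 scale, and 92.3% of them lay within 1.5-fold.

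PAX2 itself was at the level of the random-sequence probes on both arrays. Its only feature (NM_000278, HG18 chromosome 10, 102495321 to 102579688) had an intensity of 22.2 on the control array and 22.1 on the PAX2-labelled array, a log2 difference of -0.01. It lay 0.11 above the random probes on the control array and 0.19 above them on the PAX2-labelled array, brighter than 14% and 14.7% of all features. The array therefore gives no sign of PAX2 overexpression that would check the labels, and the second array is called PAX2-labelled throughout. The files do not give the positions of the 3 probes. Probes outside the transferred part of the transcript would not detect it.

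Developmental genes linked to PAX2 were mostly below the filter on both arrays. Of 25 such genes 4 were measured, and none of them differed 2-fold. SIX2, a homeobox regulator of nephron progenitors, was 1.78-fold lower on the PAX2-labelled array (log2 10.85 against 10.02). EN2, another homeobox gene, had a difference of -0.09. The median of -0.10 lay at the 17.4th percentile of matched random lists.

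Among the 11628 measured genes, 131 (1.13%) were at least 2-fold higher and 135 (1.16%) at least 2-fold lower on the PAX2-labelled array. Of these 266 genes, 143 were within the range of silent genes on the dimmer array, so their fold is only a lower bound, which can be below 2-fold. The 12 genes with the largest computed increases were LEFTY1, an antagonist of Nodal signalling, CFAP97D1, the cadherin CDH8, the semaphorin SEMA3E, WFDC12, the potassium channel subunit KCNG2, NKAIN1, the orphan receptor GPR20, the sarcomere protein MYOT, the germ-cell kinase MOS, ETFRF1 and ERICH5. The control value of 10 of these 12 was within the range of silent genes, so their rank is uncertain and only a bound can be given: NKAIN1 was at least 4.56-fold higher, LEFTY1 at least 2.02-fold and SEMA3E at least 1.63-fold. GPR20 (intensity 305 against 1423) and MOS were above that range on both arrays and were 4.66-fold and 4.48-fold higher. MOS was only just above it on the control array (log2 7.17 against 7.07). All 24 of the genes named for the largest computed increases and decreases were represented by 1 feature.

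The 12 genes with the largest computed decreases were the homeobox genes BARHL1 and EVX1, the flavin monooxygenase FMO4, CASTOR1, OSTN, the lung surfactant protein SFTPD, PRSS55, FOXR1, the complement receptor CR2, AKR1B10, ZNF749 and FAM24A. On the PAX2-labelled array 9 of these 12 were within the range of silent genes, so their rank is uncertain too, with bounds from at least 1.48-fold lower for ZNF749 to at least 5.10-fold lower for FOXR1. CASTOR1, an arginine sensor upstream of mTORC1, was 9.02-fold lower (HG18 chromosome 22, 29011107 to 29015502; intensity 2944 against 327). AKR1B10, an aldo-keto reductase, was 4.95-fold lower and CR2 5.16-fold lower. CR2 was at the edge of the silent range on the PAX2-labelled array (log2 7.156 against 7.152), so its fold is close to a bound.

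**Figure D1:**
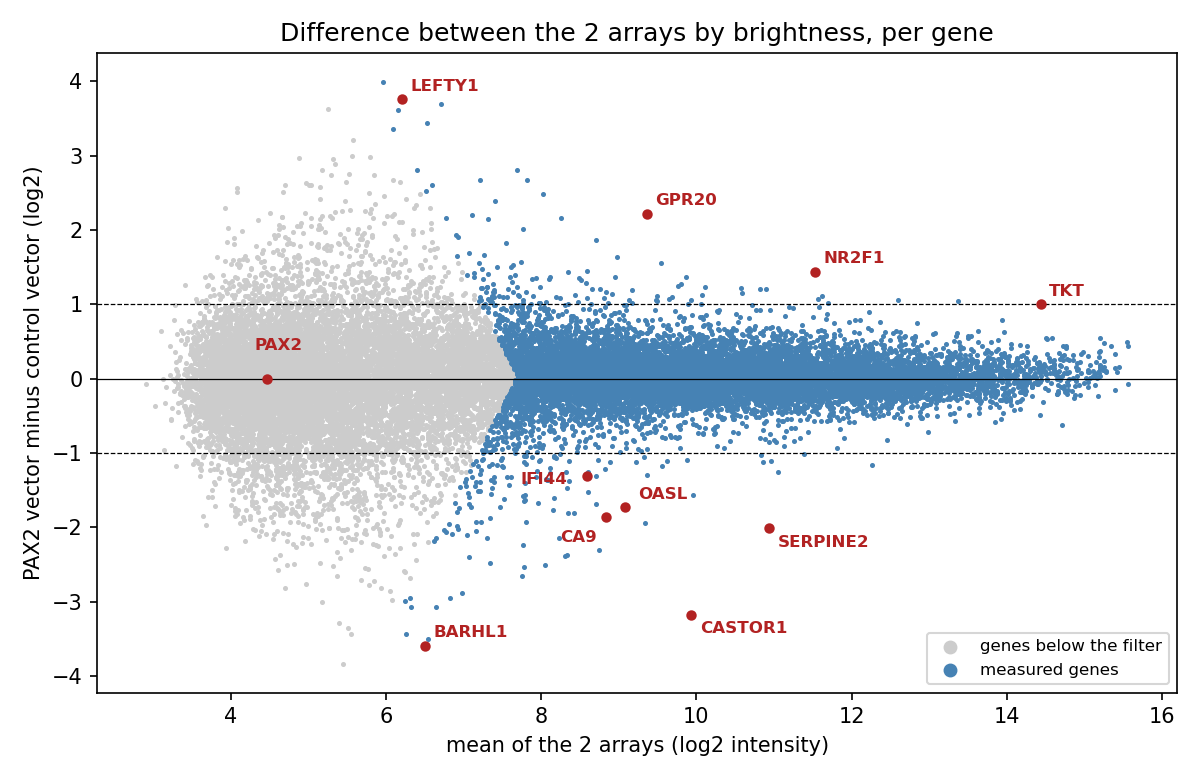
Log2 difference between the arrays (vertical axis) against their mean log2 intensity (horizontal axis), 1 point per gene; grey genes are below the filter, dashed lines mark 2-fold, and red points are genes named in the text. PAX2 lies at 4.47 with a difference of -0.01, while SERPINE2 and CASTOR1 stand apart among the brighter genes.

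Brighter genes differed less often. In the upper quartile of brightness, 21 of 5532 genes were at least 2-fold higher and 11 were at least 2-fold lower; 15 and 4 of these were protein-coding. The examples in this paragraph were chosen after their values were seen. SERPINE2, TBC1D8, URB2, NR2F1, KMT2D and TKT each had 1 feature, so no second feature could check them. SERPINE2, an inhibitor of serine proteases, was 4.04-fold lower (chromosome 2, 224548117 to 224612237; intensity 3937 against 975), and TBC1D8 and URB2 were 2.17-fold and 2.03-fold lower. NR2F1, an orphan nuclear receptor, was 2.72-fold higher (chromosome 5, 92944798 to 92955544; intensity 1799 against 4888). The transcription factors NFIC and ZBTB7B were 2.31-fold and 2.17-fold higher, with all 3 features of each above 0 (at the lowest 0.93 and 0.72). The histone methyltransferase KMT2D was 2.33-fold higher, the splicing factor U2AF2 2.09-fold and MYADM 2.30-fold. TKT, the transketolase of the pentose phosphate pathway, had intensities of 15698 on the control array and 31456 on the PAX2-labelled array, and was below 2-fold after centring (0.97), quantile normalization or loess (both 0.95 on the log2 scale). NFIC was below 2-fold in its brightest feature (0.93).

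The size of a difference depended on brightness and was seldom shared by a second feature of the gene. The SD of the difference was 0.93 in the third decile of brightness and 0.25 in the tenth, and it was 0.82 over the 376 olfactory receptor genes. In 6174 genes with at least 2 measured features, the SD attributable to a single feature was 0.31. A feature that differed 2-fold had a partner that also differed 2-fold in the same direction in 18 of 211 cases (8.53%), against 0.98% if the features were independent. The partner shared the sign in 145 of the 211. Each pair was taken in both orders, so a pair with both features 2-fold different gave 1 case per feature. Only 9 of the 50 changed genes with several features were 2-fold different in every feature, 4 higher and 5 lower. The mean over features of 5 of these 9 was within the range of silent genes on 1 array.

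Several interferon-stimulated genes were lower on the PAX2-labelled array. Of 15 measured members 3 were at least 2-fold lower, none was 2-fold higher and 12 did not reach 2-fold. OASL, an oligoadenylate synthetase-like antiviral protein, was 3.32-fold lower, with differences of -1.98 and -1.48 in its 2 features (chromosome 12, 119942477 to 119961163). IFI44 was 2.47-fold lower in its 1 feature (chromosome 1, 78888103 to 78902345). IFIT2, also with 1 feature, had a difference of -1.11 and the ubiquitin-like ISG15 of -0.90, both named after their values were seen. BST2 (0.02), OAS3 (0.37), IRF7 (0.32) and IFI6 (0.31) showed no such difference. The median of the list was -0.14, at the 1.72nd percentile of random lists, and 0.03% of random lists held 3 or more genes 2-fold lower. The median was inside the central range after quantile normalization (2.87th percentile) and loess (3.06th). It was -0.24 both with the brightest feature and with no filter on dim genes, at the 0.17th and 0.11th percentiles. With no filter 3.79% of random lists held as many 2-fold lower genes as the 4 of this list. None of the 4 members in the upper quartile of brightness differed 2-fold, and their median of -0.06 lay at the 27.7th percentile.

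**Figure D2:**
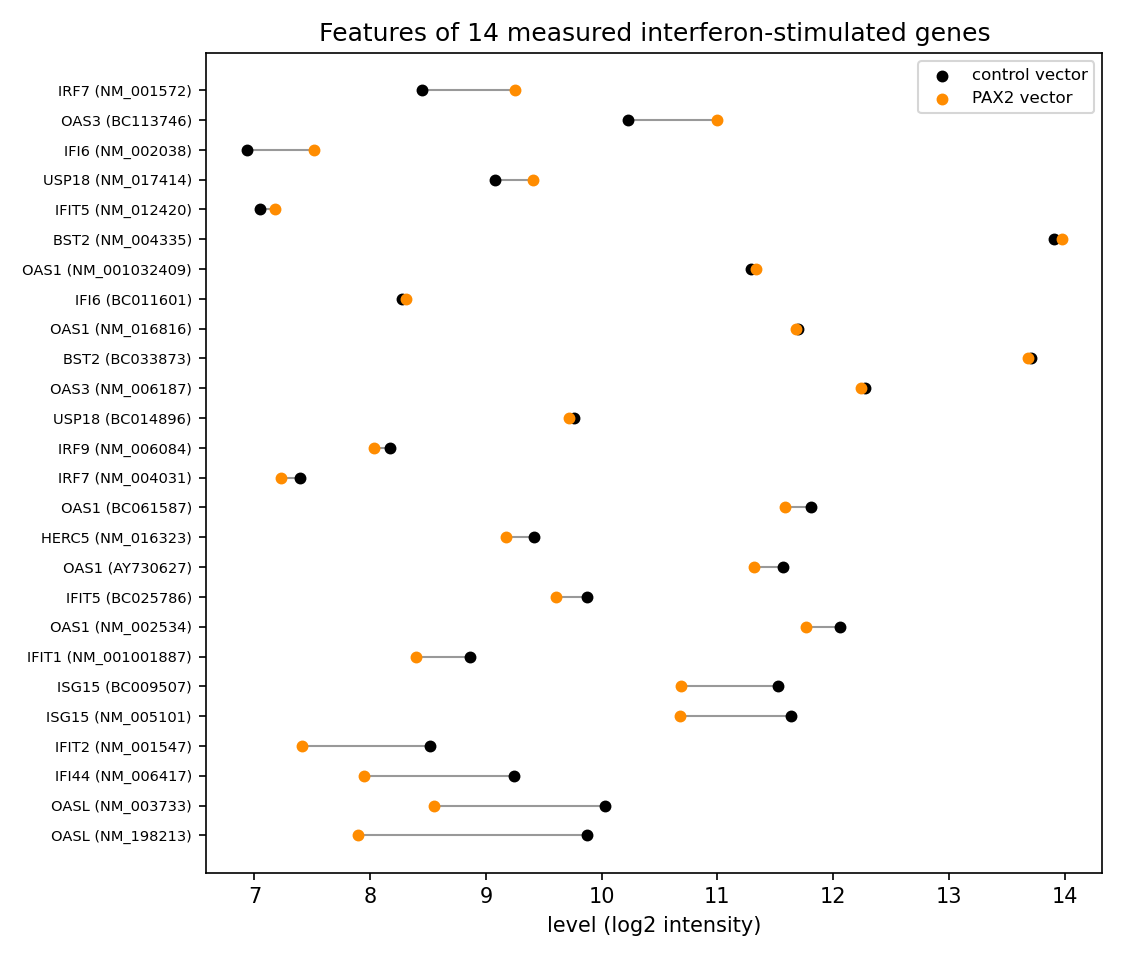
Log2 intensity (horizontal axis) of each feature of 14 of the 15 measured interferon-stimulated genes on the control array (black) and the PAX2-labelled array (orange), sorted by difference, with the feature identifier of the array design in brackets. Both features of OASL and of ISG15 lie lower on the PAX2-labelled array, while the features of IRF7, OAS3 and USP18 go both ways.

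Immediate early genes, transcription factors and regulators that respond fast to growth and stress signals, were shifted the other way by a small amount. The median of 17 measured members was 0.22, at the 99.6th percentile, with 12 above 0 and 4 below; in the upper quartile of brightness it was at the 97.0th. FOSB, with 1 feature, was 2.01-fold higher, and below 2-fold after centring, quantile normalization or loess (0.97 on the log2 scale). NR4A1 (0.90), JUND (0.58) and JUNB (0.56) did not reach 2-fold, and IER3 had a difference of -0.39.

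Genes of cholesterol synthesis showed a similar small shift. The median of 18 measured members was 0.18, at the 99.7th percentile, 15 of the 18 were above 0, and none reached 2-fold. LSS, which makes lanosterol, had the largest difference (0.48, from -0.003 to 0.83 over its 3 features), followed by MVD (0.38) and CYP51A1 (0.35). SQLE, the squalene epoxidase, had a difference of 0.19 and INSIG1 of -0.01. This list stayed outside the central range of random lists in all 5 alternatives that could move its placement.

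Of the squamous epithelial genes 12 of 28 were measured, none differed 2-fold and 10 were above 0. Their median was 0.24, at the 99.4th percentile. The basal keratin KRT5 had the largest difference (0.72, with 0.70 and 0.74 in its 2 features), followed by the transglutaminase TGM1 (0.56), and KRT6B had -0.38. With the brightest feature of each gene the median was 0.10, at the 82.3rd percentile, and with no filter it was 0.09, at the 84.4th. With no filter 2 of the 28 members were at least 2-fold lower, and 34.05% of random lists held as many. These were IVL (-2.38) and SPRR3 (-1.66), both below the filter on both arrays. Among 10 measured junction and simple keratin genes the median was -0.08 (9.41st percentile), and CRB3 had the largest difference (0.52, from 0.02 to 1.09 over its 3 features). Among 11 mesenchymal genes the median was 0.10 (83.3rd percentile, mean -0.0096) with the largest difference in CDH2 (-0.56), and VIM had 0.14.

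For Wnt target genes 7 of 14 were measured, with a median of -0.20 at the 1.46th percentile and no 2-fold difference. AXIN2, a direct feedback target, had the largest difference (0.72), against the median of the list. The sign of that median turned with the brightest feature of each gene (0.06, 66.8th percentile), and with no filter the list lay at the 41.3rd percentile. In all, 5 of the 20 lists with measured members lay outside the 2.5th to 97.5th percentile, where 1 would be expected by chance if genes of a list varied independently. Genes of a list are often regulated together, so more lists than that can fall outside by chance.

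The medians of the growth and survival lists lay inside the central range of random lists. All 26 proliferation genes were measured and none differed 2-fold; the median was 0.08 (90.2nd percentile), and TOP2A (0.46) had the largest difference, with MKI67 at 0.18 and CDK1 at -0.43. The 15 measured p53 targets had a median of 0.10 (82.8th percentile), with FAS at 0.44 and CDKN1A at -0.12. Among 7 anti-apoptotic genes the median was 0.20 (89.9th percentile) and CFLAR had the largest difference (0.49). The 11 measured pro-apoptotic genes had a median of 0.01 (43.3rd percentile) and a mean of 0.17, with BAX at 0.30 and BAK1 at -0.04. Of these 11, 1 was at least 2-fold higher and 10 did not reach 2-fold. At least as many 2-fold higher genes were held by 16.25% of random lists.

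Stress and inflammatory lists held single members past 2-fold, each with 1 feature. Among 15 heat shock genes (median 0.10, 88.6th percentile) CRYAB, a small heat shock protein, was 2.05-fold higher, and below 2-fold after quantile normalization or loess (0.98 on the log2 scale for both). Among 11 NF-kappaB and inflammatory genes (median -0.04, mean 0.17, 20.9th percentile) RELB was 2.08-fold higher. Among 15 hypoxia and glycolysis genes (median -0.05, 12.6th percentile) CA9, the hypoxia-induced carbonic anhydrase, was 3.63-fold lower (chromosome 9, 35663914 to 35671152), while VEGFA had a difference of 0.47 and SLC2A1 of -0.05. None of 16 unfolded protein and amino acid stress genes differed 2-fold (median -0.06, 14.7th percentile; PSAT1 -0.50).

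Of 7 eicosanoid synthesis genes (median -0.16, mean 0.04, 7.13th percentile) ALOX15 was at least 1.59-fold higher in 1 dim feature. None of 9 extracellular proteases and inhibitors differed 2-fold (median -0.10, 11th percentile), with ADAM17 at 0.42 and ADAM10 at 0.09. The 26 ribosomal protein genes had a median of -0.01 (14.1st percentile), with RPS6 at -0.38.

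**Figure D3:**
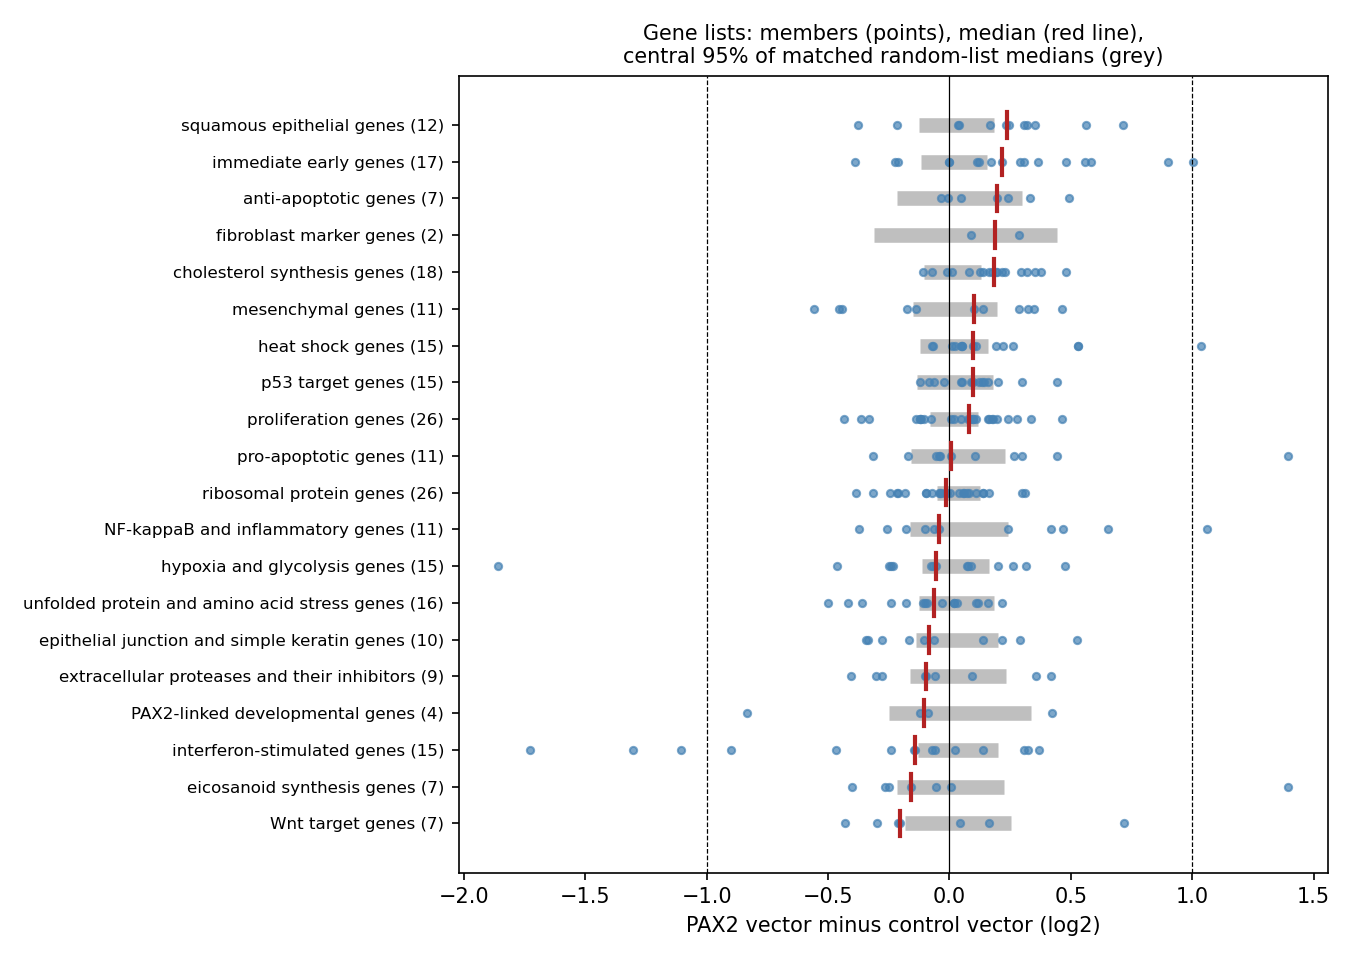
Log2 difference between the arrays for the measured members of each gene list (points, number in brackets), their median (red line) and the central range, from the 2.5th to the 97.5th percentile, of medians of matched random lists (grey bar); dashed lines mark 2-fold. The squamous, immediate early and cholesterol medians lie above the grey bar, and the interferon and Wnt medians below it.

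Markers of other cell types were not measured or did not differ 2-fold. None of 14 leukocyte and blood markers and none of 10 endothelial markers passed the filter on either array. Of 10 fibroblast markers 2 did, FBLN1 (log2 14.40 against 14.68) and DCN (difference 0.09), and their median of 0.19 lay at the 77.8th percentile.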

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

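No paired analysis was possible because each group holds 1 array. The counts of 131 higher and 135 lower genes kept within 1.5 times under the series table (identical values), centring, quantile normalization and loess. Centring gave 115 and 143, quantile normalization 114 and 144, and loess 115 and 149, so each rescaling shifted the near balance towards lower genes. The counts were 217 and 260 with the brightest feature of a gene, 755 and 960 with no filter, 21 and 11 with the 75th percentile filter, 524 and 374 at 1.5-fold, 28 and 55 at 3-fold, and 66 and 88 with an offset of 64. With 2 settings added after seeing the data they were 4 and 5 (several features, all 2-fold), and 92 and 68 with protein-coding genes only, which shifts the near balance towards higher genes. The PAX2 difference kept its value within the spread between features in the settings run for it. These were the series table, centring, quantile normalization, loess and the brightest feature. Of 161 recomputed list medians 139 moved by less than the SD of random-list medians and 1 turned sign among the lists outside the random range: Wnt targets, 0.063 with the brightest feature. With the brightest feature the medians were -0.011 (p53 targets), 0.060 (anti-apoptotic), -0.24 (interferon), 0.097 (squamous), 0.077 (junction) and -0.020 (eicosanoid). With no filter they were 0.15 (pro-apoptotic), -0.24 (interferon), 0.21 (NF-kappaB), 0.095 (squamous) and -0.0017 (Wnt); with the 75th percentile filter the pro-apoptotic median was 0.20. Means in place of medians were 0.17 (pro-apoptotic), -0.33 (interferon), 0.17 (NF-kappaB), 0.20 (heat shock), -0.0096 (mesenchymal), -0.031 (Wnt) and 0.038 (eicosanoid). The ribosomal median was -0.067 under quantile normalization and -0.062 under loess. The cause was not tested. Outside the random range the cholesterol list stayed in 5 of the 5 settings that could move it, the immediate early list in 4, the squamous list in 3, and the interferon and Wnt lists in 2 each. Unmatched random lists moved no list across the range. Of 68 genes followed singly, FOSB, TKT, NAF1, CRYAB and SPINK13 dropped below 2-fold under at least 1 scaling and NFIC with the brightest feature; none past 2-fold turned sign. Low signal over background limits the genes below the filter, PAX2 among them.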

Other observations

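The tests of this part were chosen after the result was seen, except the comparison of chromosomes, whose prediction was written before it.

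Besides OASL and MYADM, 7 genes differed 2-fold in every one of several features. Lower on the PAX2-labelled array were EBI3, a subunit of the cytokines IL-27 and IL-35 (at least 2.10-fold), MYOC (at least 1.59-fold), the G protein subunit GNG13 (at least 1.58-fold) and the mast cell tryptase TPSB2 (at least 1.69-fold). Higher were the acute-phase gene SAA2 (2.71-fold, 1.36 and 1.52 in its 2 features), FLRT1 (at least 1.75-fold) and the pseudogene NUP210P1 (1.39 and 1.73). SAA2 and TPSB2 have near-identical paralogs and NUP210P1 a parent gene, so their signal may be shared between copies, which was not tested; with protein-coding genes only, 92 genes remained at least 2-fold higher and 68 at least 2-fold lower. The means over features of EBI3, MYOC, GNG13 and TPSB2 were within the range of silent genes on the PAX2-labelled array. That of FLRT1 was within it on the control array. The means of these 5 genes therefore have only bounds, and that of EBI3 alone passes 2-fold. The brightest feature of EBI3 (-1.61), MYOC (-2.22), GNG13 (-1.61) and FLRT1 (1.06) was above that range on both arrays. Their other features and both features of TPSB2 were within it on at least 1 array.

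PAX2 at the level of the random probes is the first pattern to follow up. The feature lay 0.11 (log2) above the random probes on the control array as well, so it cannot speak for or against a swap of the arrays. Probes outside the transferred part could give this result even with strong overexpression; with 1 PAX2 feature and no probe positions, that cannot be told apart from a feature that does not respond or from cells that did not express the vector. The number of PAX2 features (1) keeps probes outside the transferred coding part open.

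The lower interferon-stimulated genes are the second. The list was picked out after its count was seen, so the test drew random lists matched to all 20 lists with measured members. The mark for measurement noise of dim features as the whole cause was set after the result was seen. It was a share of at least 5% of such sets. The share counted sets holding a list with a count of 2-fold genes, in either direction, as rare as that of the interferon list. It was 0.3%, and 1.1% with the brightest feature, but 52.5% with no filter, which adds the dimmest members. The count of 3 genes past 2-fold therefore argues against noise alone only among genes that passed the filter. The median of the list was inside the central range under quantile normalization (2.87th percentile) and loess (3.06th). It was further outside with the brightest feature (0.17th) and with no filter (0.11th), and inside with the 75th percentile filter (27.7th). Whether the list as a whole shifted therefore depends on the setting. Both features of OASL and of ISG15 were lower on the PAX2-labelled array. Transfected plasmid DNA can itself induce these genes, so a difference between the 2 cultures other than PAX2 (the amount or purity of DNA, for example) may account for them. With 1 control vector culture that explanation and an effect of PAX2 cannot be told apart.

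The third is a small shift between chromosomes. Chromosome 19, the most GC-rich human chromosome, had a median difference of 0.07 over 724 measured genes, above all 2000 matched random lists (percentile 100), and chromosomes 4 and 13, which are GC-poor, had -0.02 over 525 genes, at percentile 0. Chromosome 17 (0.06) also lay at percentile 100, while chromosome 13 alone lay at percentile 14. Chromosome 5 (percentile 1.75), which is GC-poor as well, lay below the central range, and so did chromosome 14 (percentile 0.25), which is of intermediate GC content. GC-rich chromosomes 16 and 22 lay inside it, at percentiles 89.1 and 80.1. With the brightest feature of each gene, chromosome 19 stayed at percentile 100 and chromosomes 4 and 13 moved to 10.7 (chromosome 13 alone to 38.45). With the 75th percentile filter, chromosome 19 was at percentile 100 and chromosomes 4 and 13 at 0.05 (chromosome 13 alone at 0.55). GC-dependent hybridisation or labelling may contribute, but GC content itself was not measured, so it cannot be told apart from biology that follows gene-dense chromosomes. The list shifts of about 0.2 reported for the immediate early, cholesterol and squamous genes are larger than this difference between chromosomes. A whole-chromosome median need not equal the shift of single genes, so that comparison cannot tell whether GC content contributes to the lists. This was not tested. Chromosome 19 also holds FOSB of the immediate early list, and NFIC, U2AF2 and MYADM, named above among the brighter higher genes. NR2F1, KMT2D, ZBTB7B and TKT lie on other chromosomes. Of the 724 measured genes on chromosome 19, 11 were at least 2-fold higher and 7 at least 2-fold lower. Whether the chromosome shift contributes to single genes was not tested either.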
